A study of Mus musculus with 4 samples.

How the data were processed

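Total RNA was prepared from fluorescence-sorted neutrophils of bone marrow and spleen, depleted of ribosomal RNA and made into stranded libraries, per the labels' protocols, from 2 wild-type and 2 Mif knockout samples. The labels give 100 bp paired-end sequencing with a stated target depth per sample and RNA integrity numbers averaging 9.99 with a minimum of 9.9. The run names in the labels place the wild-type libraries in lane 2 and the knockout libraries in lane 1.

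The authors deposited 1 table of FPKM values, with a column per library and a row per transcript, per the file headers. HISAT2 2.1.0, SAMtools 1.9, StringTie 2.1.4, R 3.6.1 and the genome build GRCm38 are listed in the submitters' processing notes, with no role or order. The annotation release, the strand setting and filters are not given in the sources used here, so reads of overlapping or antisense genes may not have been told apart. The same table holds the authors' fold, p-value and q-value per transcript, per the file headers. Tested on the file, the deposited fold equals 2 raised to the difference of the genotypes' mean log2(FPKM + 1) values, knockout minus wild type, to within 6.4e-14 in log2. The deposited p-value equals that of an ordinary linear model per transcript (largest difference 3.8e-12), and the deposited q-value is its Benjamini-Hochberg adjustment over the 65729 transcripts with a p-value. These authors' values were used only to describe the authors' comparison.

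FPKM was summed over the transcripts of each gene identifier and analysed as log2(FPKM + 1), so differences of low genes are understated. FPKM is a share of a library, and StringTie-type estimates divide reads among transcripts, so an exact 0 can be a failed estimate and is given as listed at 0. The files give no counts. In single-exon genes with 1 transcript, low values of FPKM times length fell on whole steps, 0.0181 and 0.0224 FPKM kb in wild-type replicates 1 and 2 and 0.00424 and 0.00463 FPKM kb in knockout replicates 1 and 2. Values within 2% of 1 step numbered 101, 121, 120 and 115, against 30, 31, 8 and 18 at a step shifted by 13%. A step may be a read or a fragment, so only relative depth was taken from it and no counting interval is given. FPKM summed to 537783, 528436, 566456 and 555540 in the same order, of which 21.7%, 19.3%, 23.8% and 20.8% came from 7SL and 7SK RNAs. Positions, exon structure, lengths, GC content and gene types came from GENCODE M21 on GRCm38, which holds 114237 of the 115220 transcripts and 47224 of the 47729 genes.

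Genes with a mean of at least 1 FPKM in either genotype were tested with limma 3.58.1 in R 4.3.3, with trended empirical Bayes moderation and no covariates, on 2 against 2 libraries. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The design was written for values per sample as found. Limma was run on data simulated for this comparison, with the spread of the 10221 genes tested and 50 changed at each of 4 folds. It called 8.4% of genes changed 1.5-fold, 60.4% of those changed 2-fold, 92.0% at 4-fold and 97.6% at 8-fold. Of its calls, 5.0% were unchanged genes. Changed genes were drawn from those with a mean log2(FPKM + 1) above 2, and folds were set on that scale. The rates therefore leave out lower genes. Every simulated library had the same spread. In the data, log2 differences had an SD of 0.337 between wild-type and 0.145 between knockout replicates, so the rates may not hold here.

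The 32 gene lists were fixed before the data were examined: MIF axis; azurophil, specific and gelatinase or secretory granules; mature neutrophils; cell cycle; type I interferon; interferon gamma and MHC class II; inflammatory NF-kB targets; IL-23 and IL-17; Dectin-1 sensing; NADPH oxidase; glycolysis and hypoxia; p53 and apoptosis; chemotaxis and adhesion; granulopoietic transcription factors; respiratory chain; ribosomal proteins; immediate early and heat shock genes; mitochondrially encoded genes; sex-linked genes; 10 other cell types; and genes beside Mif. The symbols Mpig6b, Slc2a11 and Rgl4 of these lists matched no gene name used here. A symbol with more than 1 gene identifier was counted once per identifier, as was Itgam in the specific granule and chemotaxis lists. Lists with at least 3 tested genes, 25 in all, were compared with other genes by camera in limma at a preset correlation of 0.01, adjusted over the 25. With an estimated correlation, camera called 0 of the 25. Fry in limma, which tests whether a list's genes move on balance one way without comparing them with other genes, called 1 list, the B cell list (adjusted p = 0.0248). Genes within 10 Mb of Mif were compared with the rest by Fisher's exact test, two-sided.

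Genes were named by a rule fixed before the data were examined: Mif and the MIF axis; per direction the 10 genes with the largest log2 difference among those past the threshold, with at least 1 FPKM in the higher genotype and both libraries of one genotype above both of the other; and per list up to 4 members with the lowest p. Predicted genes named Gm with a digit, names ending in Rik and names holding -ps were not eligible. I830127L07Rik, Ly6c2, Cd79a, Ms4a1, Ddx3y, Eif2s3y and Kdm5d, and the genes named only in the closing observations, were chosen outside it.

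The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a group mean of at least 5 FPKM, transcripts in place of genes, the replicate number as a block, rescaling to the same sum (TPM), quantile normalization, each library left out in turn, no trend, other thresholds, adjustment over named genes, an estimated correlation for lists and windows of 5 and 20 Mb around Mif. Those added after seeing the data were a correction of each library for GC content and length by loess, array weights, an ordinary linear model, centring on the library median, protein-coding genes only and no immunoglobulin genes.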

Results

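RNA of neutrophils from SKG mice was sequenced in 4 libraries, 2 from wild-type mice and 2 from mice lacking Mif, the gene of macrophage migration inhibitory factor, a secreted cytokine. SKG mice carry a mutation in the T cell signalling kinase gene Zap70 on a BALB/c background and develop arthritis and spondylitis after injection of curdlan, a fungal beta-glucan bound by the receptor Dectin-1. Cells were sorted from bone marrow and spleen 8 weeks after curdlan. The labels do not give the proportions, which may differ between the genotypes. The files hold FPKM values (fragments per kilobase, scaled to library size) for 115220 transcripts of 47729 genes, and the question addressed is which transcripts differ between Mif-deficient and wild-type neutrophils in this disease model. Genes listed above 0 numbered 18329 and 18358 in wild-type replicates 1 and 2 and 20556 and 20557 in knockout replicates 1 and 2. The smallest steps between low FPKM values put the relative depth of the libraries at 1.23 in wild-type replicate 1, 5.28 in knockout replicate 1 and 4.83 in knockout replicate 2, with wild-type replicate 2 set to 1. The knockout libraries were thus sequenced more deeply, and the labels' run names place them in lane 1 and the wild-type libraries in lane 2, so genotype, depth and lane cannot be separated. Nothing in the labels says whether the replicates were separate animals, so p-values measure only the spread between these samples, which may be technical.

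Mif was listed at 0 FPKM in both knockout libraries and at 0.882 and 2.88 FPKM in wild-type replicates 1 and 2. The gene (ENSMUSG00000033307) lies on the minus strand of chromosome 10, from 75859353 to 75860240 of GRCm38, and its annotated transcript has 3 exons and 544 nucleotides. The wild-type values correspond to 26.4 and 70 of the steps estimated for those libraries. At this transcript's length, 3 such steps equal 0.10 and 0.123 FPKM in the wild-type libraries and 0.0234 and 0.0255 FPKM in the knockout libraries. On the log2(FPKM + 1) scale the difference was -1.43 ± 0.35 (SE, n = 2 per group), which did not pass the threshold over all genes (limma, Benjamini-Hochberg adjusted p = 0.161), the wild-type libraries themselves differing widely. In the authors' deposited table the Mif transcript had a fold of 0.370 and an adjusted p of 0.558. None of the other MIF axis genes passed in the 2 against 2 comparison, and 1 of the 7 axis genes tested, Mif itself, had an unadjusted p under 0.05. Cd74, the MIF receptor subunit and MHC class II invariant chain, stood at 4.97 and 10.8 FPKM in wild-type and 11.5 and 11.9 FPKM in knockout libraries. The MIF homologue Ddt stood at 1.2 and 2.0 against 2.1 and 2.1 FPKM. The chemokine receptors Cxcr2 (455 and 500 against 449 and 499 FPKM) and Cxcr4 (163 and 192 against 193 and 201 FPKM) and the co-receptor Cd44 (334 and 332 against 320 and 355 FPKM) overlapped or nearly met between genotypes. Cops5, a signalosome subunit that binds MIF, did not overlap and did not pass (12.0 and 12.3 against 10.6 and 11.3 FPKM). Ackr3, a further chemokine receptor, was listed at 0 in 3 of the 4 libraries.

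Knockout libraries held more transcripts of Ly6c1, Ly6g and Ly6a, of the granule serine protease gene Prtn3 and of the NKG2D ligand genes Raet1d and Raet1e, and fewer of Igkc, Ighm and Jchain. Ly6c1, a GPI-anchored antigen, rose from 50.8 and 49.4 FPKM in the wild-type libraries to 146 and 150 FPKM in the knockout libraries. That is a log2 difference of 1.54 ± 0.07 (SE, n = 2 per group; limma, Benjamini-Hochberg adjusted p = 0.0226). Ly6g, the antigen by which mouse neutrophils are commonly identified, rose from 519 and 491 to 918 and 936 FPKM (0.88 ± 0.07, limma adjusted p = 0.0364). Summed with its neighbouring pseudogene I830127L07Rik, the difference was 0.21 (limma adjusted p = 0.196). Prtn3, the azurophil granule protease proteinase 3, rose from 3.56 and 3.92 to 10.8 and 9.49 FPKM (1.23 ± 0.10, limma adjusted p = 0.0365). The immunoglobulin kappa constant gene Igkc fell from 103 and 88.7 to 17.3 and 20.4 FPKM (-2.29 ± 0.12, limma adjusted p = 0.0226), and Jchain, which joins secreted IgM and IgA, fell from 10.6 and 9.43 to 1.86 and 2.29 FPKM (-1.84 ± 0.11, limma adjusted p = 0.0261).

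**Figure D1:**
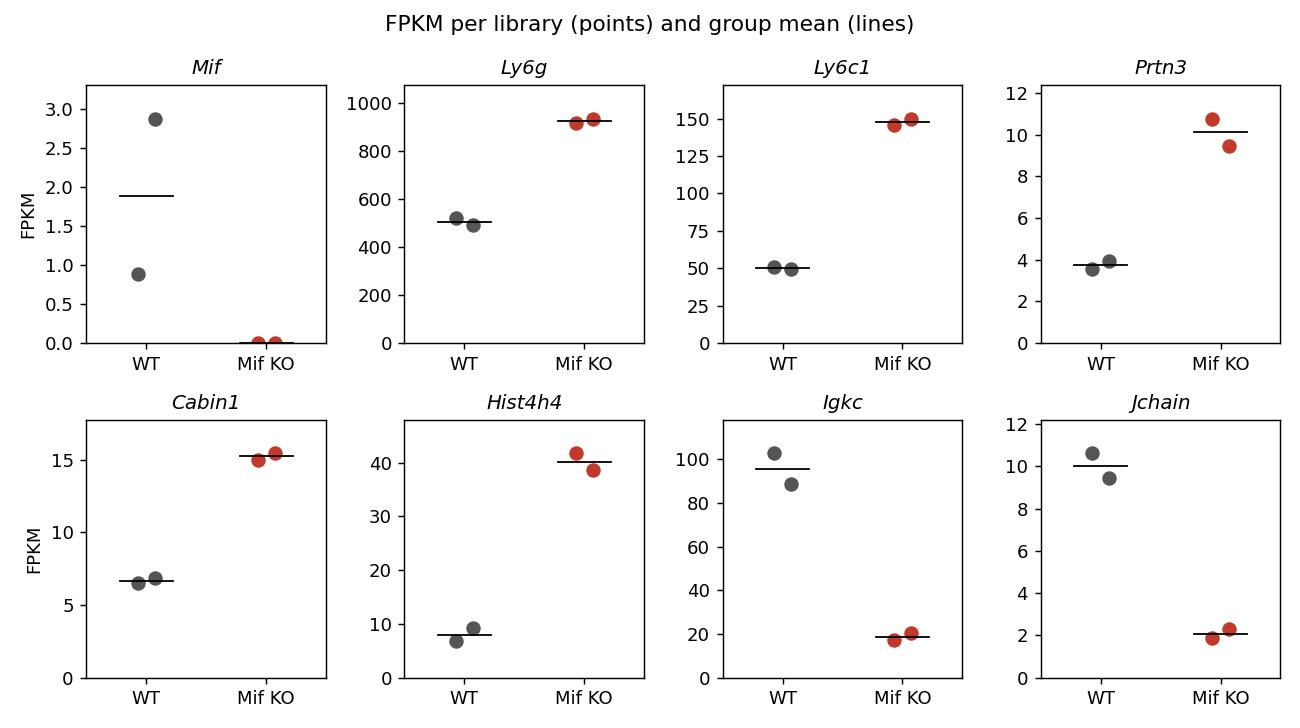
FPKM of 8 genes, on axes from 0, in the 2 wild-type (WT, grey) and 2 knockout (Mif KO, red) libraries; each point is a library and each line a group mean. Mif is at 0 in both knockout libraries, Igkc falls from 103 and 88.7 to 17.3 and 20.4 FPKM, and Ly6c1 rises from 50.8 and 49.4 to 146 and 150 FPKM.

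Of 10221 genes with a group mean of at least 1 FPKM in either genotype, 35 passed the threshold (limma, Benjamini-Hochberg), 16 higher and 19 lower in the knockout. At an unadjusted p under 0.05 there were 853 higher and 977 lower, and among the 8444 protein-coding genes tested 798 higher and 344 lower. Among genes past the threshold, predicted genes aside, the largest increases on the log2(FPKM + 1) scale beyond those of Ly6c1 and Prtn3 were in Hist4h4, a replication-dependent histone H4 gene (6.73 and 9.18 to 41.7 and 38.6 FPKM), and Tlcd2 (0.605 and 0.550 to 4.47 and 4.47 FPKM). Rmrp, the RNA of the ribonuclease MRP complex (140 and 125 to 430 and 393 FPKM), and the sphingomyelinase gene Smpd5 (0.0634 and 0.119 to 1.87 and 2.22 FPKM) rose too. So did Ly6a, the stem cell antigen Sca-1 (0.421 and 0.634 to 2.63 and 2.69 FPKM), and Mgat5, an N-glycan branching enzyme (3.22 and 3.06 to 7.95 and 8.21 FPKM). Raet1d and Raet1e, which encode ligands of the activating receptor NKG2D, rose from 0.594 and 0.317 to 2.87 and 3.23 FPKM and from 0.547 and 0.511 to 2.30 and 2.57 FPKM. With a pseudocount of 0.1, Raet1d (limma adjusted p = 0.0671), Ly6a (0.0616) and Iglj1 (0.0624) no longer passed. Among genes past the threshold, predicted genes and other names not eligible aside, the 10 largest decreases on that scale were all in immunoglobulin genes or Jchain. Ighm, the IgM heavy chain constant gene, fell from 82.1 and 60.0 to 16.3 and 18.4 FPKM, and the lambda constant gene Iglc1 fell from 8.75 and 12.8 to 0.433 and 0.744 FPKM. The other 6 were Igkv1-117, Igkv1-110, Igkv10-96, Iglv1, Iglj1 and Ighj3, with log2 differences from -2.41 for Igkv1-117 to -1.64 for Igkv10-96. In all, 13 of the 75 immunoglobulin genes tested passed, each lower in the knockout. Ly6, Raet1, histone and immunoglobulin genes have near-identical relatives, and reads may have been divided among them. The Ly6-related pseudogene I830127L07Rik, beside Ly6g on chromosome 15, fell from 587 and 630 to 360 and 365 FPKM (limma adjusted p = 0.0490), and Ly6c2 stood at 635 and 602 against 662 and 670 FPKM. A correction for GC content and length, chosen after seeing the data, left 0 genes past the threshold (lowest limma adjusted p 0.0501), with 2038 genes at an unadjusted p under 0.05 and a log2 difference of 1.50 ± 0.07 for Ly6c1. Leaving out either knockout library also left 0, and leaving out wild-type replicate 1 or 2 gave 2675 or 2938.

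**Figure D2:**
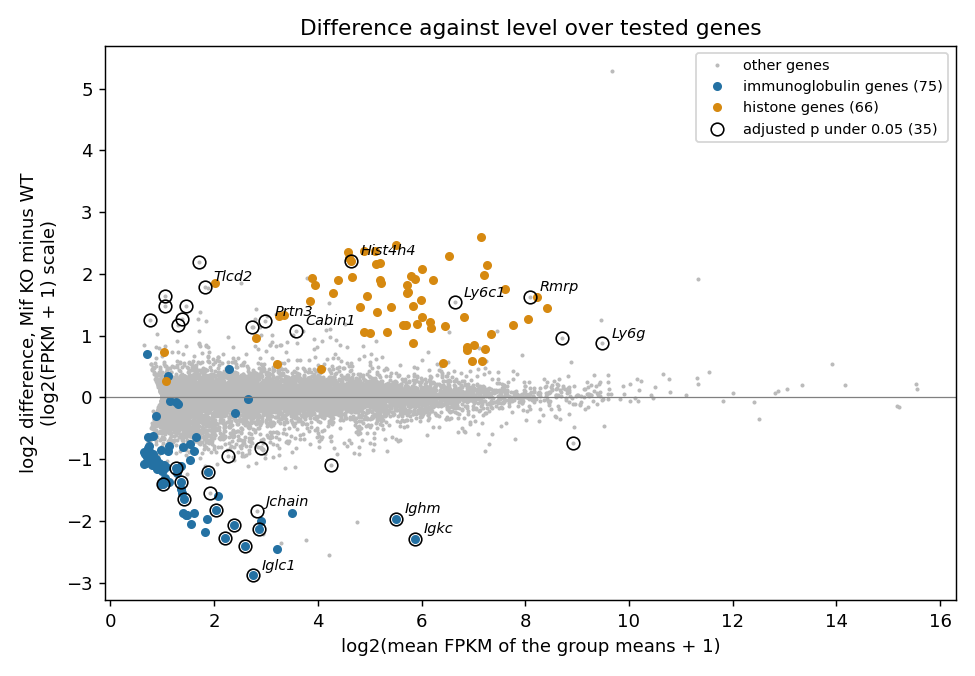
Log2 difference between knockout and wild type (vertical axis, on the log2(FPKM + 1) scale) against the level of each gene (horizontal axis, log2 of the mean FPKM plus 1) for the 10221 genes tested; blue, 75 immunoglobulin genes; orange, 66 histone genes; circles, the 35 genes past the threshold. Immunoglobulin genes lie mostly below 0 (median -1.10) and histone genes above 0 (median 1.47).

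In the authors' deposited table, 45 transcripts had an adjusted p under 0.05, 37 higher and 8 lower in the knockout. Of these, 42 had no library at 1 FPKM or more and 34 were listed at 0 in both wild-type libraries, the ones estimated to be shallower.

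Cell cycle genes were higher in knockout libraries as a group, the shares of marrow and spleen cells being unknown. Differences were also positive in 8 of 8 erythroid and 9 of 10 monocyte and macrophage genes, against 2 of 4 progenitor genes. Of the 30 S and G2/M phase genes tested, 28 had a positive difference, with a median of 0.30 on the log2 scale; 0 passed over all genes, 18 passed, all upward, adjusted over the list alone, and 19 had an unadjusted p under 0.05. The mitotic kinase Plk1 stood at 12.8 and 13.6 FPKM in wild-type and 19.7 and 19.4 FPKM in knockout libraries. The replicative helicase subunit Mcm7 stood at 7.16 and 7.57 against 10.2 and 10.7 FPKM, the helicase subunit Mcm5 at 6.96 and 7.40 against 9.72 and 9.77 FPKM. The ubiquitin-conjugating enzyme Ube2c stood at 25.2 and 24.2 against 32.1 and 32.0 FPKM. The list stood apart from other genes with limma's camera at a preset correlation of 0.01 (adjusted p = 1.0e-09), and not with an estimated correlation (adjusted p = 0.808).

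Interferon-stimulated genes lay higher in the knockout, by an amount that depended on the wild-type library. Of 34 type I interferon genes tested, 32 had a positive difference (median 0.28; camera adjusted p = 2.3e-07, and adjusted p = 0.823 with an estimated correlation); 0 passed over all genes, 0 passed adjusted over the list alone, and 14 had an unadjusted p under 0.05. Slfn5 stood at 9.16 and 12.9 against 22.7 and 26.5 FPKM. The translation inhibitor gene Ifit1 stood at 8.43 and 13.3 against 19.3 and 22.6 FPKM and its relative Ifit2 at 5.08 and 5.01 against 6.51 and 7.36 FPKM. Of 19 interferon gamma and MHC class II genes, 18 had a positive difference (median 0.48; camera adjusted p = 5.1e-05, and adjusted p = 0.823 with an estimated correlation), 0 passed over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05. The peptide transporter Tap1 stood at 22 and 31.5 against 41.9 and 40.4 FPKM. The GTPase Irgm1 stood at 17.3 and 25 against 30.6 and 34.5 FPKM and Igtp at 18.6 and 29.9 against 37.6 and 40.6 FPKM, and the immunoproteasome subunit Psmb8 at 23 and 25.7 against 30.2 and 28.4 FPKM. The median of the interferon gamma and MHC class II list was 0.18 without wild-type replicate 1 and 0.87 without wild-type replicate 2, and that of the type I list 0.18 and 0.40. Markers of other cell types lay higher alongside, 9 of 10 monocyte and macrophage genes and 8 of 8 erythroid genes, with wild-type replicate 1 lowest for the macrophage gene C1qa.

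**Figure D3:**
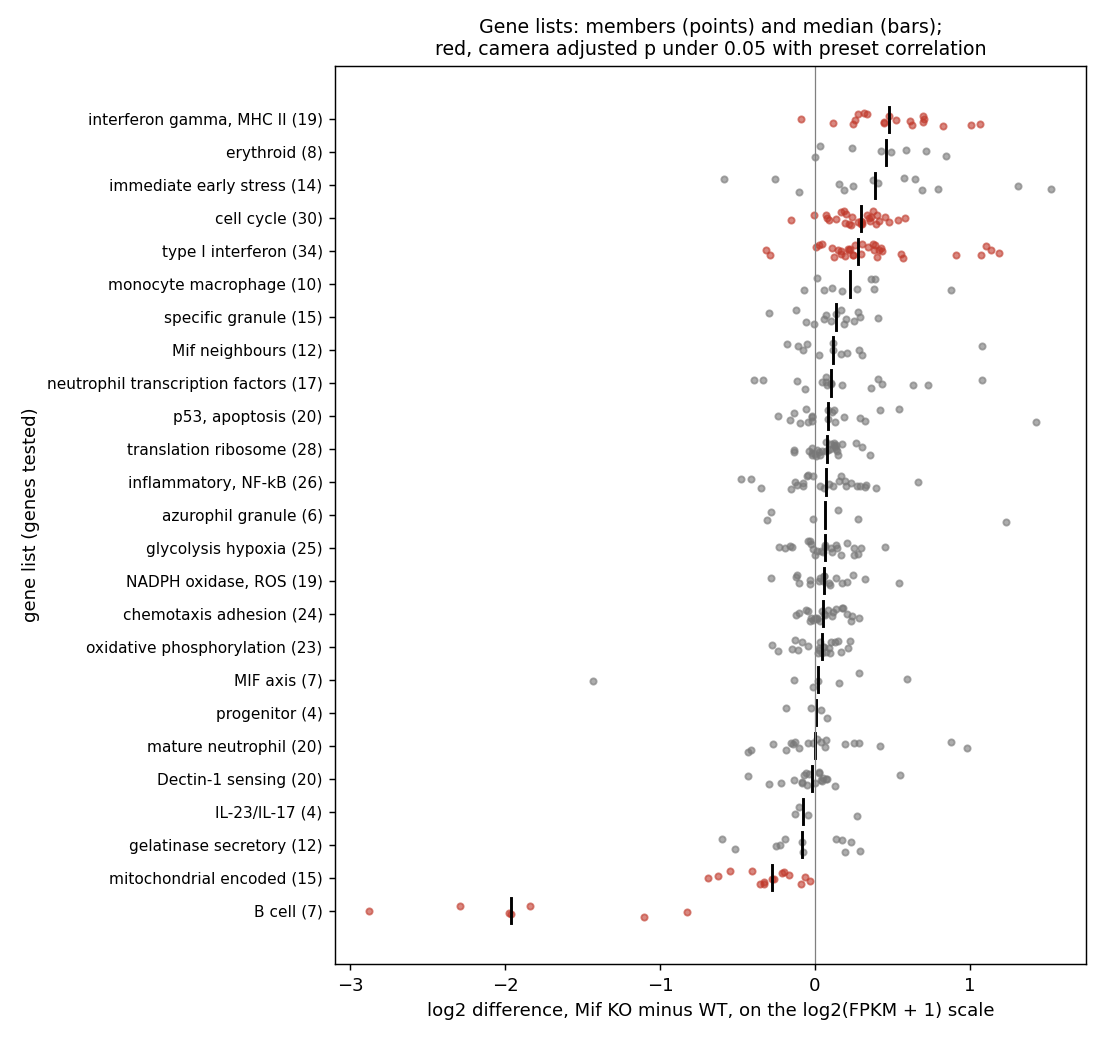
Log2 difference between knockout and wild type (horizontal axis) of every tested member (points) of the 25 gene lists with at least 3 tested genes (vertical axis), with the list median (bars); red marks the 5 lists with a camera adjusted p under 0.05 at the preset correlation. The B cell list lies lowest (median -1.96) and the interferon gamma and MHC class II list highest (median 0.48).

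None of the 4 lists of granule and mature neutrophil genes passed as a group with camera (adjusted p = 0.362 azurophil, 0.0838 specific, 0.966 gelatinase and 0.966 mature), and 2 of their genes passed over all genes. Among 20 genes of mature neutrophils, 1 passed over all genes and adjusted over the list alone, Ly6g, which did not pass when summed with its pseudogene, and 10 had positive differences. Other members with low unadjusted p were the histone citrullinating enzyme Padi4 (224 and 233 against 271 and 273 FPKM), the chemokine receptor Cxcr1 (4.22 and 4.73 against 5.52 and 5.78 FPKM) and Retnlg (2932 and 2234 against 3347 and 3489 FPKM). Among 6 azurophil granule genes, 1 passed over all genes and adjusted over the list alone, Prtn3. The serine protease Prss57 stood at 2.77 and 2.27 against 3.03 and 3.51 FPKM. Among 15 specific granule genes, 0 passed over all genes or adjusted over the list alone and 5 had an unadjusted p under 0.05, all upward. Among them were Olfm4 (355 and 368 against 435 and 451 FPKM), the collagenase Mmp8 (723 and 691 against 828 and 856 FPKM) and Ngp (17763 and 16697 against 19869 and 19663 FPKM). Among 12 gelatinase granule and secretory vesicle genes, 0 passed over all genes and 1 passed adjusted over the list alone, downward, the cystatin-like Stfa2l1 (166 and 161 against 97.4 and 119 FPKM). The gelatinase Mmp9 stood at 1066 and 997 against 1258 and 1263 FPKM.

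No gene of the lists for NADPH oxidase and reactive oxygen, glycolysis and hypoxia, p53 and apoptosis, chemotaxis and adhesion, Dectin-1 sensing, inflammatory NF-kB targets, IL-23 and IL-17, granulopoietic transcription factors or the respiratory chain passed over all genes or adjusted over the list alone (limma). At an unadjusted p under 0.05 they held 3 of 19, 5 of 25, 5 of 20, 5 of 24, 1 of 20, 3 of 26, 0 of 4, 8 of 17 and 3 of 23 genes tested. Over all genes tested, 1830 of 10221 had such a p. The granulopoietic transcription factors Cebpa (2.87 and 3.49 against 4.32 and 4.41 FPKM) and Gfi1 (4.65 and 7.16 against 9.32 and 9.69 FPKM) stood higher, and Runx1 (22.2 and 19.2 against 14.9 and 15.9 FPKM) and Fosl2 (109 and 121 against 87.4 and 94.4 FPKM) lower, in the knockout libraries. At the level of transcripts Runx1 turned to a difference of 0.17 and the NF-kB regulator Bcl3 to 0.40. The pattern recognition receptor Tlr2 stood at 50.6 and 50 against 39.1 and 42.4 FPKM, and Nfkbiz, also an NF-kB regulator, at 50.5 and 66.2 against 38.8 and 43.9 FPKM and Bcl3 at 36.6 and 42.3 against 31.8 and 29.6 FPKM. The oxidase subunit Ncf1 stood at 645 and 620 against 747 and 751 FPKM.

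Immunoglobulin genes and Jchain, which make up the tested part of the B cell list, differed between the genotypes. Lists of the other cell types tested with camera did not pass. All 7 B cell and plasma cell genes tested were lower in the knockout (median -1.96; camera adjusted p = 5.9e-11, and adjusted p = 0.465 with an estimated correlation), 4 of them past the threshold over all genes, Igkc, Jchain, Iglc1 and Ighm, and 7 adjusted over the list alone. Mature B cell surface genes were near the floor in every library: Cd79a stood at 0.161 and 0.155 against 0.0694 and 0.0763 FPKM, and Ms4a1 was at or under 0.0214 FPKM. Erythroid genes had a median difference of 0.46 over 8 genes, all positive, and monocyte and macrophage genes 0.23 over 10, with 9 positive (camera adjusted p = 0.0888 and 0.110). Wild-type replicate 1 was lowest for the erythroid band 3 gene Slc4a1 (0.461 and 3.06 against 3.29 and 3.48 FPKM) and for the macrophage complement gene C1qa (1.69 and 3.10 against 3.23 and 3.43 FPKM). Progenitor genes had a median of 0.0039 over 4 genes. T cell, natural killer cell, dendritic cell, eosinophil and mast cell, platelet and stromal lists held at most 2 tested genes each and were not tested as groups. Mitochondrially encoded genes were lower in the knockout, 15 of 15 (median -0.28; camera adjusted p = 2.6e-05, and adjusted p = 0.823 with an estimated correlation), with 0 past the threshold over all genes and 3 adjusted over the list alone. The cytochrome b gene mt-Cytb stood at 78.4 and 78.1 against 61.7 and 62.3 FPKM and mt-Nd1 at 20.7 and 20.2 against 15.7 and 15.9 FPKM. Without wild-type replicate 1 that median was -0.0976 (camera adjusted p = 0.105). The 14 immediate early and heat shock genes tested had a median of 0.39, with 11 positive (camera adjusted p = 0.251). Of them 0 passed over all genes. Adjusted over the list alone 1 passed, downward, the chaperone Hspa8 (185 and 208 against 125 and 136 FPKM). Jun stood at 2.33 and 5.31 against 10.7 and 10.1 FPKM. Ribosomal protein genes had a median of 0.0779 over 28 genes, with 0 past the threshold on either adjustment. Xist, the RNA of the inactive X chromosome, stood at 22.9 and 23.5 against 17.4 and 18.9 FPKM. The Y-linked genes Ddx3y and Eif2s3y were listed at 0 in all 4 libraries. Kdm5d, also Y-linked, stood at 0.00298 and 0.00634 against 0.00244 and 0 FPKM.

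Near the Mif locus, Cabin1, a calcineurin inhibitor gene 95 kb from Mif on chromosome 10, rose from 6.50 and 6.82 to 15 and 15.4 FPKM (1.08 ± 0.08, n = 2 per group; limma adjusted p = 0.0296). It was the only 1 of 12 tested genes on the fixed list of Mif neighbours to pass over all genes or adjusted over the list alone. Within 10 Mb on each side of Mif, 2 of 134 genes passed, Cabin1 and Prtn3 (79874476 to 79883174 of chromosome 10), against 33 of 10045 elsewhere (odds ratio 4.60, Fisher's exact test, two-sided, p = 0.0772). Within 5 Mb it was 2 of 82 (odds ratio 7.62, Fisher's exact p = 0.0321) and within 20 Mb 2 of 216 (odds ratio 2.81, Fisher's exact p = 0.170), and at an unadjusted p under 0.05 the odds ratio within 10 Mb was 1.28 (Fisher's exact p = 0.256). Whether the colonies differ in DNA around Mif or elsewhere was not tested. Such a difference would change what the values of Cabin1, Prtn3, Raet1d and Raet1e mean.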

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

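The correction for GC content and length, array weights, the ordinary linear model, centring, protein-coding genes only and no immunoglobulin genes were chosen after seeing the data; the other alternatives were fixed beforehand, and those written for counts or for a table of comparisons only were not run. Of 16 genes higher and 19 lower in the knockout, counts of 0 and 0 came from no filter, an adjusted threshold of 0.01, the GC and length correction and the ordinary linear model, where 3032, 1830, 2038 and 1318 genes had an unadjusted p under 0.05 (limma, or the ordinary model). A pseudocount of 0.1 gave 13 and 14, with Hist4h4 at 2.34, Tlcd2 at 2.76, Smpd5 at 3.5 and, not past the threshold, Raet1d at 2.55. A group mean of at least 5 FPKM gave 8 and 8, transcripts in place of genes 36 and 11, an adjusted threshold of 0.1 42 and 77, an unadjusted p under 0.05 with a 2-fold minimum 85 and 62, array weights 45 and 78, and no immunoglobulin genes 10 and 3. TPM gave 17 and 30 (36.2% higher, against 45.7% at first), quantile normalization 12 and 9 (57.1% higher), and protein-coding genes only 12 and 1. Named genes past the threshold that lost their call numbered 3 with a pseudocount of 0.1, 18 with transcripts, 8 with quantile normalization and 22 with no filter. Transcripts shared 3 genes with the 35, TPM 35 and quantile normalization 20. Leaving out 1 library gave 0 to 1623 higher and 0 to 1752 lower, a lone library being assumed to vary like the other genotype; knockout replicates resemble each other most, so fits without a wild-type replicate have the smallest spread. Replicate numbers did not pair the samples (correlation of same-numbered deviations 0.0065), and the replicate block gave 18 and 16 genes, 29 of them among the 35, with 8 lists called, 5 of them of other cell types or quality.

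The cause of the following changes was not tested. The Mif difference was -4.10 with a pseudocount of 0.1 (limma adjusted p = 0.106), ranged from -1.96 to -1.43 with a library left out, and passed without wild-type replicate 1 and, at -1.43, at an unadjusted p under 0.05 with a 2-fold minimum; with wild-type replicate 2 left out, or a mean of at least 5 FPKM, Mif was below the filter. Other MIF axis genes past the threshold numbered 0 to 3 with a library left out. Lists called, 5 at first, numbered 4 to 11 with a library left out, 8 with no filter and 0 with an estimated correlation. Lists of other cell types or quality, 2 at first, numbered 1 to 5 with a library left out, 4 with no filter, 1 for protein-coding genes only, 1 with no immunoglobulin genes and 0 with an estimated correlation. The estimated correlation left the medians at -1.96 (B cell), 0.30 (cell cycle), 0.28 (type I interferon), 0.48 (interferon gamma and MHC class II) and -0.28 (mitochondrially encoded), each no longer past the threshold, and with a library left out the mitochondrial median ranged from -0.356 to -0.0976. The odds ratio near Mif, 4.60, passed at 6.07 with a pseudocount of 0.1, 9.86 at a mean of at least 5 FPKM, 12.1 for protein-coding genes only, 7.62 within 5 Mb and 2.16 without wild-type replicate 2 (Fisher's exact p = 1.8e-05), and ranged from 0.881 to 2.16 with a wild-type library left out; where no gene passed it could not be computed. Among genes that did not pass, signs turned for Cops5 (0.0069), Bcl3 (0.40), Il17ra (0.11), Vav3 (0.034), Runx1 (0.17), Siglecf (-0.0065), Ifitm1 (-0.13) and Myb (0.082) with transcripts; Ifitm1 (-0.037) and Pecam1 (-0.042) with TPM; Retnlg (-0.054), Tcf4 (0.0096) and Ifitm1 (-0.035) with quantile normalization; Ifitm1 (-0.015) and Pecam1 (-0.014) with the GC correction; and Pecam1 (-0.0022) with centring. With a library left out, ranges spanning 0 were -0.0993 to 1.20 for Clec4n, -0.296 to 0.215 for Tcf4, -0.011 to 0.084 for Ifitm1, -0.0096 to 0.037 for Pecam1, -0.0993 to 0.0069 for Il6ra, -0.168 to 0.049 for Cd3d, -0.261 to 0.027 for Ear2 and -0.090 to 0.032 for Myb.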

Other observations

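Histone genes, taken as those with names starting with Hist and not among the fixed lists, mostly lay higher in knockout libraries. As a group they were not tested against other genes. Of 66 histone genes tested, 63 had an unadjusted p under 0.05, all upward, and 1, Hist4h4, passed over all genes (limma, Benjamini-Hochberg); the median log2 difference was 1.47. Their FPKM summed to 1898 and 3393 in wild-type replicates 1 and 2 and to 7564 and 6033 in knockout replicates 1 and 2. The linker histone genes Hist1h1e (122 and 193 against 420 and 330 FPKM) and Hist1h1c (84.2 and 131 against 232 and 197 FPKM) and the H4 gene Hist1h4h (36.7 and 80 against 277 and 215 FPKM) were among them. Near-identical copies may share reads, which leaves the quartiles of 1.08 and 1.91 a description of the family rather than of single genes. Rpph1, the RNA of ribonuclease P, stood at 854 and 1336 against 4182 and 3878 FPKM, and the RNase P-like Rprl3 at 280 and 287 against 586 and 527 FPKM.

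Wild-type replicate 1 stood apart from the other 3 libraries in single transcripts. The mitochondrial leucyl-tRNA synthetase gene Lars2 stood at 45.5 FPKM there and at 2.11, 1.51 and 1.36 FPKM in the others, the mitochondrial ribosomal RNA mt-Rnr2 at 52.9 against 19.2, 20.5 and 18.5 FPKM, and AC157822.1, annotated as a microRNA gene, at 0.0487 against 885, 1155 and 1216 FPKM. Over the genes tested, the correlation of log2 values was 0.983 between the wild-type and 0.997 between the knockout libraries, and wild-type replicate 2 correlated at 0.984 and 0.987 with the knockout libraries. On the leading principal component (64.8% of the variance) wild-type replicates 1 and 2 lay at -25.0 and -5.80 and the knockout libraries at 16.5 and 14.2, and on the next (28.9%) at 10.0 and -18.9 against 6.08 and 2.83, so each wild-type library stood apart on one of them.

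Chosen after the result was seen were the GC and length correction and the tests of plasma cell genes, B cell genes, the cell cycle list, small RNA genes, the summed Ly6 pairs and the chromosome 15 window. With 4 libraries there are 3 splits into pairs, too few for a share under 0.05; 1 split, the real one, gave as many as 35 genes and the highest other gave 0.

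Immunoglobulin genes were lower in the knockout libraries, with a median of -1.10 over 75 genes and summed FPKM of 496 and 399 against 97.2 and 107. The GC and length correction left the median at -1.12 with quartiles of -1.60 and -0.87, which argues against that trend as the whole cause. The correction ended every single-gene call, with a lowest limma adjusted p of 0.0501, while Igkc kept a difference of -2.32 ± 0.14 against -2.29 ± 0.12 before. A candidate explanation is plasma cells, or their RNA, in the wild-type sort. Of 15 plasma cell genes other than immunoglobulins and Jchain, 6 had both wild-type libraries above both knockout libraries, against 2.92 for genes of similar level (exact one-sided p = 0.0527, with genes taken as independent), among them Mzb1 (0.535 and 0.617 against 0.0772 and 0.0409 FPKM), Txndc5 (0.691 and 0.458 against 0.116 and 0.161 FPKM) and Pou2af1 (0.375 and 0.369 against 0.0733 and 0.0825 FPKM). For mature B cells the count was 4 of 15 against 2.2 (exact p = 0.162), so neither cell type was decided by these genes, and whether the Mif genotype changes how many such cells there are was not tested.

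For the histone genes, the GC and length correction left a median of 1.36 with quartiles of 0.93 and 1.70, so that trend does not account for the whole difference. The cell cycle list had an upper quartile of 0.37, below the lower quartile of the histone genes. That list mixes S and G2/M phase genes, so this argues only against a larger share of cycling cells that raises both phases alike. Small nuclear and small nucleolar RNA genes, which also lack poly(A) tails, showed no gain as a class. Their median was -0.39, with an upper quartile of -0.19 over 168 genes. Single RNAs of this kind, Rmrp, Rpph1 and Rprl3, were higher, and other noncoding classes were lower too (microRNA genes -0.41, sense-intronic genes -0.47). The fall was thus not particular to small nuclear and nucleolar RNA, and it cannot decide whether other RNA without poly(A) tails was gained. The difference in lane and estimated depth between the genotypes and the genotype itself remain open, since the design does not separate them.

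On chromosome 15, Ly6a, Ly6c1 and Ly6g passed, and Ly6e (45.7 and 73.6 against 116 and 128 FPKM) and Ly6i did not. The summed FPKM of Ly6g and the pseudogene I830127L07Rik was higher in the knockout by 0.21 ± 0.06 in log2 (limma adjusted p = 0.196), against 0.88 for Ly6g alone. That sum did not pass, and differences of similar size were seen in other abundant genes, such as Ngp (0.20) and Mmp8 (0.25). It therefore cannot decide whether reads moved between the pair are the whole cause. How much of the Ly6g difference such reads carry was not tested. The summed FPKM of Ly6c1 and Ly6c2 was higher by 0.28 ± 0.07 (limma adjusted p = 0.159), and Ly6c2 was not lower. The Ly6c sum did not pass either, and its difference was also near those of other abundant genes. It therefore cannot decide whether reads moved between Ly6c1 and Ly6c2. Another candidate is a stretch of DNA that differs between the colonies: without Ly6 and immunoglobulin genes, 4 of 88 genes between 70 and 80 Mb (Smpd5, Exosc4, Dgat1 and Mpst) against 80 of 10009 elsewhere had an adjusted p under 0.1 (odds ratio 5.91), but the best of 276 windows was as extreme in 45.3% of 1000 shuffles, so the window, picked after a scan, cannot be told apart from chance. Sequence variants in the reads would decide it.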
